A study of Arabidopsis thaliana with 12 samples.

How the data were processed

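RNA was sequenced from dissected inflorescence meristems of Arabidopsis in 12 libraries, from 2 genotypes and 2 air humidities with 3 replicates each. Total RNA was taken with a plant RNA kit and libraries with an Illumina RNA library kit, per the labels' protocols. Whether the kit marks strand, and whether the counting used strand, is not given in the sources used here, so reads of overlapping antisense genes cannot be told apart. Reads were trimmed with Trimmomatic 0.39, aligned with HISAT2 2.2.1 to TAIR10 and assigned to genes with featureCounts 2.0.6, per the submitters' processing notes. The deposited count table holds whole-number read counts per gene and library, not normalized, as the authors made them. The deposited TPM table holds TPM values (transcripts scaled for length and depth) made by the authors, per the file headers.

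The count table listed 25424 genes, each with at least 1 count in col0 low replicate 1, while each of the other libraries had 884 to 1278 genes at 0. Genes silent in that library are thus not analysed here, which can hide genes that appear only in high humidity or in pip2. The TPM table gave no value for 2537 genes, and its totals came to 90.0% to 91.3% of what complete TPM columns sum to. Of the gene identifiers, 25326 matched the NCBI annotation of TAIR10.1, which was used for names and for the order of neighbouring genes. A gene symbol was found for 9665, and no coordinates are given because the builds differ in name.

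Groups and replicate numbers came from the sample titles, and all count columns were used. The tests, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 21897 tested genes. Libraries were scaled by TMM, with factors of 0.972 to 1.04. The quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was fitted to all 12 libraries with 1 mean per group. It gave the humidity response within each genotype, the genotype difference at each humidity and the interaction. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the tested genes of a comparison, and the threshold was 0.05. Fold changes are high minus low humidity, or pip2 minus col0. The humidity responses share no library with each other, nor do the genotype differences.

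Library totals ran from 17850187 to 28445060 counts. Within groups the log2 CPM correlated at 0.982 to 0.990 across genes. The chi-square statistic per degree of freedom between replicates of a group was 5.02 to 11.9, so none was a repeat of another replicate of its group. The 10 most abundant genes took 2.89% to 3.42% of the counts, chloroplast genes 0.00690% to 0.0101% and mitochondrial genes 0.0153% to 0.0278%. The test was tried on simulated counts with 200 changed genes of 21897, drawn from genes with a mean of at least 1 CPM. At absolute log2 fold changes of 0.5, 1 and 2 it recovered 47.8%, 88.1% and 97.0% for the humidity response in col0 (3.73% of calls false). It recovered 41.8%, 83.6% and 98.5% for the genotype difference at low humidity (4.49% false), and 17.9%, 64.2% and 98.5% for the interaction (6.98% false). These shares do not cover genes below 1 CPM. Many more genes were called for humidity in col0 (6614) than were changed in the simulation, so the shares may differ there.

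Genes are named by a fixed rule. It takes PIP2;5 and, from each comparison of 2 groups, the 10 genes with the highest and the 10 with the lowest log2 fold change. These have to be past the threshold, with a mean of at least 1 CPM, no overlap between the groups and a gene symbol. For the interaction it takes 5 and 5. From each list it takes up to 4 members past the threshold with the smallest adjusted p, or the member with the smallest p where none passed. The chromosome 1 neighbours and the genes of the last section were chosen after their values were seen.

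The 22 lists held 426 genes, of which 408 were in the table and 383 were tested. They covered PIP and TIP aquaporins, ABA and dehydration, heat shock and chaperones, salicylic acid and immunity, jasmonate, rapid touch and wound response, meristem and boundary regulators, and floral identity. They also covered anther, photosynthetic, vascular, wax and cutin, stomatal, cell cycle, cytokinin, auxin, expansin and xyloglucan, iron, nutrient status, clock and flavonoid genes. Each list was tested by camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and adjustment over the lists of a comparison. Camera with an estimated correlation and fry stood beside it. In 22 simulated lists of 20 genes, camera called the 1 list shifted by 0.4 log2 (adjusted p = 1.58e-23) and 0 others. The simulated genes varied independently, while the estimated correlation was 0.848 in the photosynthetic list and 0.613 in the touch list. The simulation therefore does not test calls on lists whose genes vary together.

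The alternatives were DESeq2 size factors, no filter and a stricter filter (at least 1 CPM in 3 libraries and a mean of at least 5), and the DESeq2 1.42.0 Wald test. Others were limma on log2(TPM + 1) and log2(TPM + 0.1), a replicate block, an absolute log2 fold change of at least 1, only the 6 libraries compared, and each library left out in turn. In the TPM alternatives 161 tested genes without a TPM value were left out. For the overlaps an adjusted p under 0.1 was also tried. The titles give no source of a pairing. Deviations from the group means correlated over 0.1 in every same-numbered pair of col0 low with col0 high (r = 0.22, 0.17 and 0.37) and with pip2 low (0.20, 0.16 and 0.21). A different-numbered pair, col0 low replicate 3 with pip2 high replicate 1, also reached 0.22. No chance level was computed, so a pairing of those groups is possible but not established. Among same-numbered pairs the lowest r was -0.03 between the pip2 groups and -0.0092 between the groups in high humidity. The counts without the chromosome 1 neighbours, and without the 4 libraries numbered 1, were added after seeing the data.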

Results

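Gene expression was measured by RNA sequencing of inflorescence meristems, the growing shoot tips that form flowers, dissected from Arabidopsis thaliana. The 12 libraries fell into 4 groups of 3: wild type (col0) and a mutant, called pip2 here, each in low or in high air humidity. The labels write the mutant as pip2 or pip2d and the series' design text as pip2;5, and PIP2;5 encodes an aquaporin of the plasma membrane, a channel for water. Replicates 1, 2 and 3 held 20611944, 18010889 and 20384128 counts in col0 at low humidity and 19440154, 21655990 and 28445060 at high humidity. In pip2 they held 19482546, 19513029 and 20030505 counts at low humidity and 17850187, 23088975 and 18466396 at high humidity. Libraries of a group correlated at 0.982 to 0.990 across genes (log2 CPM), and the biological coefficient of variation was 10.3%. The library pip2 high replicate 2 correlated more with col0 high replicate 1 (0.986) than with its own replicates (0.984 and 0.985), and it was kept. The labels do not say whether replicates were separate plants or pools, so p-values measure the spread between these libraries. Values after gene names are log2 fold changes ± SE from edgeR with 3 libraries per group, and "rose" and "fell" mark an adjusted p under 0.05. The SE was derived as the absolute log2 fold change over the square root of the F statistic of the quasi-likelihood test. Levels are in CPM (counts relative to the scaled library total), as mean ± SD over 3 libraries.

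PIP2;5 itself was read first, because it checks the labels. In col0 it stood at 70.8 ± 0.876 CPM in low humidity and 50.8 ± 1.33 in high humidity. In pip2 it stood at 0.785 ± 0.348 and 0.962 ± 0.204, from 11 to 25 counts per library, so all 6 mutant libraries lay far below all 6 wild-type libraries. The log2 difference between genotypes was -6.48 ± 0.15 in low humidity (adjusted p = 6.08e-15) and -5.70 ± 0.14 in high humidity (adjusted p = 3.29e-14). Within col0 the gene fell with high humidity (log2 fold change -0.48 ± 0.09, adjusted p = 0.000835), while within pip2 its value was 0.30 ± 0.24 with an adjusted p of 0.46.

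**Figure D1:**
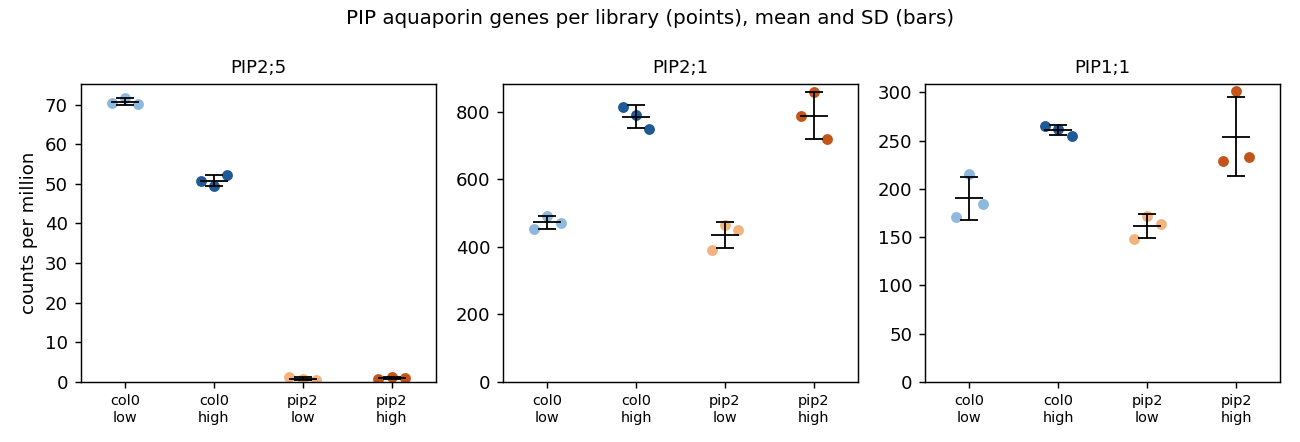
CPM (vertical axis, linear, from 0) of PIP2;5, PIP2;1 and PIP1;1 in the 4 groups, with 1 point per library and bars for mean and SD (n = 3). PIP2;5 lies between 49.5 and 71.8 in the col0 libraries and between 0.548 and 1.19 in the pip2 libraries, and PIP2;1 is higher in high humidity in both genotypes.

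The first comparison asks how the wild-type meristem responds to air humidity. In high humidity 15 of 16 heat shock genes, 15 of 20 photosynthetic genes and the morning genes of the circadian clock rose. Dehydration, wax, jasmonate and cell cycle genes fell in 16 of 30, 12 of 29, 7 of 16 and 14 of 30 cases. Of the lists called by camera in col0, the heat shock list alone kept its call with an estimated correlation. The named genes that rose included FTM1 (AT1G43800, 4.64 ± 0.42), SEN1 (AT4G35770, 4.30 ± 0.29), which is a gene of dark-grown and ageing tissue, MYB51 (AT1G18570, 4.15 ± 0.47), a regulator of indole glucosinolates, and IGMT4 (AT1G21130, 4.23 ± 0.80), a methyltransferase of the same pathway. RAV2 (AT1G68840, 4.22 ± 0.71), ERF104 (AT5G61600, 3.89 ± 0.79), CAF1a (AT3G44260, 3.56 ± 0.99) and PR4 (AT3G04720, 3.34 ± 0.44) rose as well. PAP85 (AT3G22640) had 0 to 2 counts per library in low humidity and 53 to 72 in high humidity, so no fold is given for it. The named genes that fell included the dehydrin gene LTI30 (AT3G50970, -4.56 ± 0.32), the terpene synthase genes TPS03 (AT4G16740, -4.18 ± 0.66) and TPS02 (AT4G16730, -2.46 ± 0.58), the plastid glucose-phosphate transporter GPT2 (AT1G61800, -2.91 ± 0.20), FAR7 (AT5G22420, -2.62 ± 0.32), COR15B (AT2G42530, -2.49 ± 0.11), LEA7 (AT1G52690, -2.27 ± 0.36), ChlAKR (AT2G37770, -2.17 ± 0.21), JAL34 (AT3G16460, -2.05 ± 0.34) and RTFL5 (AT5G59510, -2.03 ± 0.21). In all, 6614 of 21897 tested genes passed (3127 higher and 3487 lower), of which 516 rose and 191 fell at least 2-fold. The libraries of the groups did not overlap for 44.8% of tested genes, where chance gives 10%.

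Among the gene lists, heat shock and chaperone genes moved most in col0. Of 16 tested members 15 rose, and 15 rose when adjusted over the list alone, with a median log2 fold change of 1.72. Camera gave the heat shock list adjusted p = 8.49e-13, and adjusted p = 0.0175 with an estimated correlation. The disaggregase HSP101 (AT1G74310, 1.24 ± 0.09), HSP90.1 (AT5G52640, 2.42 ± 0.15), HSP70 (AT3G12580, 2.69 ± 0.16) and HSP17.6A (AT5G12030, 3.70 ± 0.38) were the members with the smallest adjusted p. In the ABA and dehydration list 16 of 30 members fell and 5 rose (18 and 6 adjusted over the list alone). Camera gave the dehydration list adjusted p = 0.00292, and adjusted p = 0.382 with an estimated correlation. It was led by COR15A (AT2G42540, -1.63 ± 0.07), COR15B, LTI30 and P5CS1 (AT2G39800, -0.94 ± 0.07), the last a proline synthesis enzyme. Jasmonate genes fell in 7 of 16 cases and none rose (7 and 1 adjusted over the list alone), among them LOX2 (AT3G45140, -1.22 ± 0.10) and OPR3 (AT2G06050, -0.72 ± 0.07), enzymes of jasmonate synthesis, JAZ10 (AT5G13220, -1.08 ± 0.16) and JAZ5 (AT1G17380, -0.68 ± 0.12). Camera gave the jasmonate list adjusted p = 0.0122, and adjusted p = 0.454 with an estimated correlation. Of 17 rapid touch and wound genes 12 rose (13 adjusted over the list alone), with ERF1A (AT4G17500, 1.61 ± 0.30), MPK3 (AT3G45640, 0.93 ± 0.17), TCH3 (AT2G41100, 3.16 ± 0.53) and ZAT10 (AT1G27730, 3.21 ± 0.62). Camera gave the touch list adjusted p = 7.15e-05, and adjusted p = 0.382 with an estimated correlation. The touch list differed within groups too: relative to the col0 low mean it averaged 0.72 log2 in col0 high replicate 1 but 1.85 and 1.75 in replicates 2 and 3.

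The surface, growth and light lists of col0 moved as follows. Wax and cutin genes fell in 12 of 29 cases and 1 rose (12 and 1 adjusted over the list alone), including CER4 (AT4G33790, -0.85 ± 0.08), a fatty acyl reductase of wax alcohols, and LTPG2 (AT3G43720, -0.71 ± 0.07). Camera gave the wax and cutin list adjusted p = 0.00312, and adjusted p = 0.461 with an estimated correlation. Cell cycle genes fell in 14 of 30 cases and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 0.000392, and adjusted p = 0.461 with an estimated correlation). The sliding clamp genes PCNA1 (AT1G07370, -0.90 ± 0.11) and PCNA2 (AT2G29570, -0.62 ± 0.08) and the ribonucleotide reductase gene TSO2 (AT3G27060, -0.81 ± 0.11) fell, and the cyclin gene CYCD3;2 (AT5G67260, 0.41 ± 0.05) rose. Photosynthetic genes rose in 15 of 20 cases (15 adjusted over the list alone), with LHCB1.1 (AT1G29920, 0.58 ± 0.07), LHCB1.4 (AT2G34430, 2.37 ± 0.20), LHCA1 (AT3G54890, 0.54 ± 0.08) and LHCB2.2 (AT2G05070, 0.50 ± 0.07). Camera gave the photosynthetic list adjusted p = 6.91e-07, and adjusted p = 0.382 with an estimated correlation. Expansin and xyloglucan enzyme genes fell in 7 of 18 cases and 2 rose (7 and 2 adjusted over the list alone), with XTH15 (AT4G14130, 0.87 ± 0.08) up and EXPA10 (AT1G26770, -0.99 ± 0.11), EXPA15 (AT2G03090, -0.72 ± 0.11) and EXPA5 (AT3G29030, -0.82 ± 0.12) down. Camera gave the expansin and xyloglucan list adjusted p = 0.0394, and adjusted p = 0.382 with an estimated correlation. LHCB1 and small heat shock genes have close copies, so reads may have been split among them.

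Of 16 clock genes 6 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.188). The morning genes LHY (AT1G01060, 1.61 ± 0.07), RVE4 (AT5G02840, 1.13 ± 0.08), CCA1 (AT2G46830, 1.02 ± 0.08) and RVE8 (AT3G09600, 0.89 ± 0.08) rose. Among the PIP aquaporins 4 of 13 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.646), with PIP2;1 (AT3G53420, 0.73 ± 0.08) and PIP1;1 (AT3G61430, 0.46 ± 0.10) up and PIP2;5 and PIP2;8 (AT2G16850, -0.67 ± 0.15) down. The tonoplast aquaporins TIP2;1 (AT3G16240, 0.40 ± 0.06), TIP1;2 (AT3G26520, 0.41 ± 0.06) and TIP1;1 (AT2G36830, 0.18 ± 0.07) were the 3 of 7 that rose, also adjusted over the list alone (camera adjusted p = 0.142). Flavonoid genes fell in 5 of 10 cases, also adjusted over the list alone (camera adjusted p = 0.0614), among them TT7 (AT5G07990, -1.02 ± 0.10), CHI (AT3G55120, -0.40 ± 0.07), FLS1 (AT5G08640, -0.47 ± 0.08) and CHS (AT5G13930, -0.35 ± 0.09).

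Few regulators of the meristem itself passed in col0. Of 28 meristem and boundary regulators 5 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.214): the receptor kinase gene CLV1 (AT1G75820, 0.55 ± 0.06), CNA (AT1G52150, 0.31 ± 0.06) and HAM3 (AT4G00150, 0.33 ± 0.08) rose and BAM2 (AT3G49670, -0.29 ± 0.06) fell. Of 19 floral identity genes 1 fell, SEP2 (AT3G02310, -0.19 ± 0.06), and none did adjusted over the list alone (camera adjusted p = 0.938). The stomatal list had 5 of 12 members up and 1 down (6 and 1 adjusted over the list alone, camera adjusted p = 0.150), with TMM (AT1G80080, 0.43 ± 0.11), EPFL9 (AT4G12970, 0.38 ± 0.11) and SPCH (AT5G53210, 0.40 ± 0.13) up and SCRM (AT3G26744, -0.19 ± 0.05) down. Auxin genes rose in 1 of 22 cases and fell in 4, also adjusted over the list alone, with GH3.5 (AT4G27260, 1.14 ± 0.08) up and IAA3 (AT1G04240, -1.12 ± 0.13), TAA1 (AT1G70560, -0.61 ± 0.11) and IAA19 (AT3G15540, -0.68 ± 0.12) down. Camera gave the auxin list adjusted p = 0.0763, or 0.0301 with a replicate block, and adjusted p = 0.382 with an estimated correlation and no block. Cytokinin genes gave 1 rise, ARR9 (AT3G57040, 0.34 ± 0.12), and 1 fall, AHK4 (AT2G01830, -0.40 ± 0.11), of 15 (0 and 1 adjusted over the list alone, camera adjusted p = 0.938). Iron genes rose in 3 of 7 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 0.122), with the ferric reductase gene FRO3 (AT1G23020) up from 16.3 ± 2.53 to 43 ± 3.51 CPM and FER1 (AT5G01600, -0.59 ± 0.12), a ferritin gene, down. Nutrient status genes rose in 3 of 12 cases, also adjusted over the list alone (camera adjusted p = 0.155), among them AT1G04770 (0.44 ± 0.10) and SDI1 (AT5G48850, 0.56 ± 0.18). Salicylic acid and immunity genes split, with 2 of 15 up and 3 down, also adjusted over the list alone (camera adjusted p = 0.692): PBS3 (AT5G13320, 0.48 ± 0.10) and CBP60G (AT5G26920, 3.22 ± 0.76) rose and WRKY54 (AT2G40750, -1.09 ± 0.26) and SARD1 (AT1G73805, -1.16 ± 0.38) fell.

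The vascular and anther lists had rises and no falls past the test in col0. Vascular genes rose in 4 of 14 cases, also adjusted over the list alone (median log2 fold change 0.30, camera adjusted p = 0.0614), with CESA8 (AT4G18780, 0.42 ± 0.08), CESA4 (AT5G44030, 0.41 ± 0.10), CESA7 (AT5G17420, 0.31 ± 0.09) and MYB46 (AT5G12870, 0.69 ± 0.19). Anther genes rose in 2 of 17 cases, also adjusted over the list alone, while the list's median log2 fold change was -0.48 (camera adjusted p = 0.233): GRP17 (AT5G07530, 0.55 ± 0.13) and GRP19 (AT5G07550, 0.47 ± 0.14) rose, the latter at adjusted p = 0.0618 with a replicate block. Of the named calls in col0, 15 of 96 were lost without at least 1 library, among them CAF1a, TIP1;1, SARD1, SEP2, SPCH, SCRM, EPFL9, ARR9, SDI1, GRP19, CESA7 and MYB46.

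**Figure D2:**
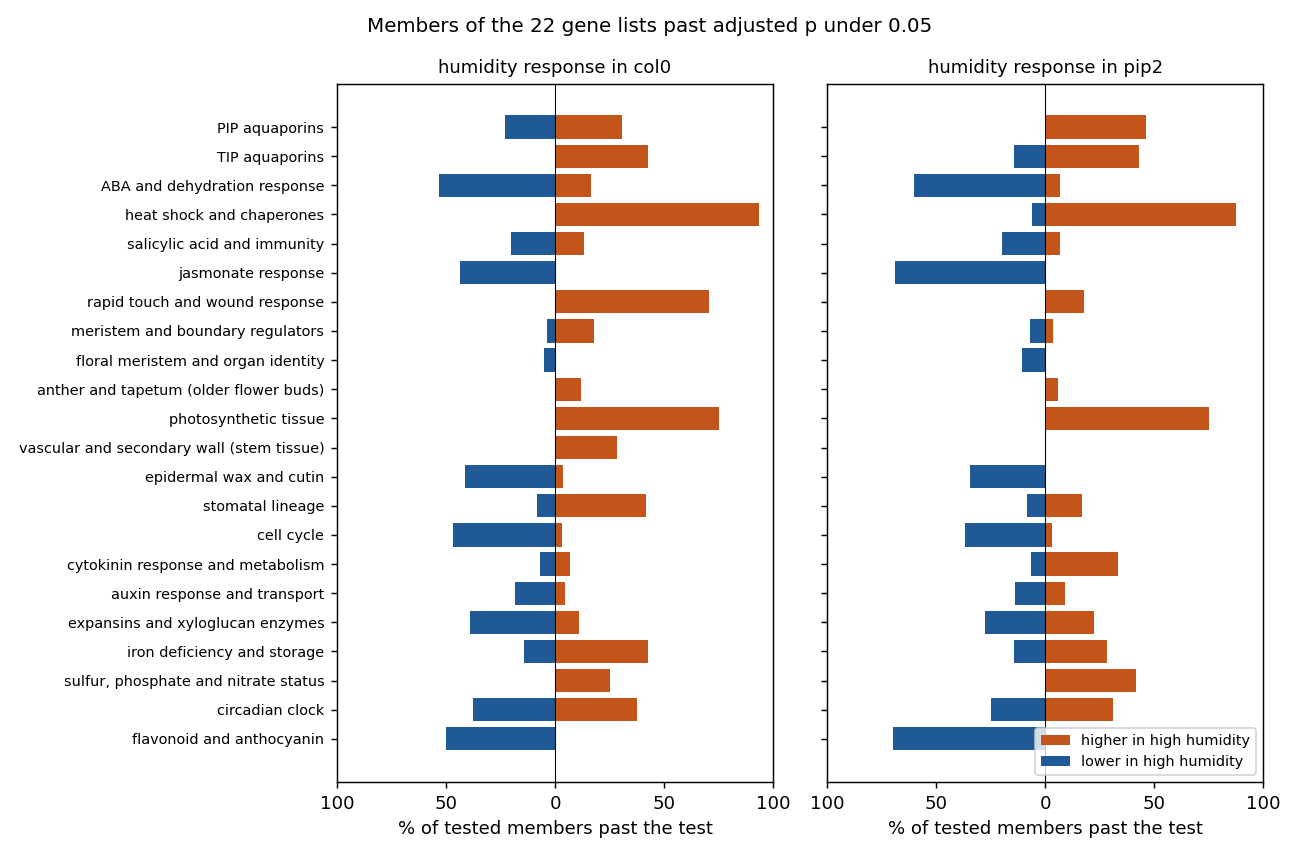
Share of the tested members of each of the 22 gene lists (percent, horizontal axis) that passed adjusted p under 0.05 in col0 and in pip2, to the right when higher in high humidity and to the left when lower. Heat shock genes have 15 of 16 members to the right in col0 and 14 of 16 in pip2, and jasmonate genes have 7 and 11 of 16 to the left.

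The same question was put to pip2. There 14 of 16 heat shock genes, 15 of 20 photosynthetic genes and clock morning genes rose. Dehydration, jasmonate, flavonoid and wax genes fell in 18 of 30, 11 of 16, 7 of 10 and 10 of 29 cases, and the heat shock list alone kept its camera call with an estimated correlation. SEN1 (4.70 ± 0.28), FTM1 (4.21 ± 0.41), HSP17.6A (3.66 ± 0.44), BT5 (AT4G37610, 3.65 ± 0.20), ABCB21 (AT3G62150, 2.93 ± 0.24), HSP70 (2.91 ± 0.17), IGMT4 (2.90 ± 0.68), CML38 (AT1G76650, 2.72 ± 0.56) and DIN10 (AT5G20250, 2.67 ± 0.23) rose, and PAP85 went from 0 to 1 counts per library to 90 to 188. The genes that fell included LTI30 (-4.49 ± 0.32), TPS03 (-3.55 ± 0.62), GPT2 (-3.39 ± 0.21), TAT3 (AT2G24850, -3.34 ± 0.53), RD29A (AT5G52310, -2.90 ± 0.21), IGMT5 (AT1G76790, -2.81 ± 0.24), IPMI2 (AT2G43100, -2.77 ± 0.39), TPS02 (-2.54 ± 0.63), FMO GS-OX3 (AT1G62560, -2.53 ± 0.26) and COR15B (-2.52 ± 0.11). In all 5294 genes passed, 2684 higher and 2610 lower, of which 426 rose and 212 fell at least 2-fold. The groups did not overlap for 38.1% of tested genes, where chance gives 10%.

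Heat shock genes rose in 14 of 16 cases in pip2 and 1 fell, also adjusted over the list alone (median 1.83). Camera gave the heat shock list adjusted p = 2.85e-11, and adjusted p = 0.0262 with an estimated correlation. They included HSP101 (1.13 ± 0.09), HSP90.1 (2.09 ± 0.16) and the heat shock factor HSFA2 (AT2G26150, 1.51 ± 0.17). Dehydration genes fell in 18 of 30 cases and 2 rose (20 and 2 adjusted over the list alone), led by COR15A (-1.79 ± 0.07) and P5CS1 (-1.44 ± 0.07). Camera gave the dehydration list adjusted p = 9.45e-09, and adjusted p = 0.149 with an estimated correlation. Jasmonate genes fell in 11 of 16 cases, also adjusted over the list alone, with LOX2 (-1.35 ± 0.10), OPR3 (-0.92 ± 0.07), JAZ5 (-1.49 ± 0.12) and LOX3 (AT1G17420, -0.82 ± 0.08). Camera gave the jasmonate list adjusted p = 2.76e-08, and adjusted p = 0.149 with an estimated correlation. Flavonoid genes fell in 7 of 10 cases, also adjusted over the list alone, with TT7 (-0.90 ± 0.10) and TT8 (AT4G09820, -1.26 ± 0.30). Camera gave the flavonoid list adjusted p = 0.000213, and adjusted p = 0.149 with an estimated correlation. Photosynthetic genes rose in 15 of 20 cases, also adjusted over the list alone (camera adjusted p = 2.76e-08, and adjusted p = 0.389 with an estimated correlation), with LHCB1.4 (2.25 ± 0.20). Wax and cutin genes fell in 10 of 29 cases (11 adjusted over the list alone), with CER4 (-0.55 ± 0.08) and MAH1 (AT1G57750, -0.53 ± 0.10). Camera gave the wax and cutin list adjusted p = 0.00452, and adjusted p = 0.507 with an estimated correlation. Cell cycle genes fell in 11 of 30 cases and 1 rose (14 and 2 adjusted over the list alone), with TSO2 (-0.63 ± 0.11), PCNA1 (-0.57 ± 0.11) and MCM7 (AT4G02060, -0.51 ± 0.11) lower. Camera gave the cell cycle list adjusted p = 0.00686, and adjusted p = 0.599 with an estimated correlation.

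Of 13 PIP aquaporins 6 rose and none fell, also adjusted over the list alone, with PIP2;1 (0.86 ± 0.08), PIP1;1 (0.66 ± 0.11), PIP1;3 (AT1G01620, 0.33 ± 0.06) and PIP1;2 (AT2G45960, 0.30 ± 0.06). Camera gave the PIP list adjusted p = 0.00201, and adjusted p = 0.193 with an estimated correlation. Of 7 TIP aquaporins 3 rose and 1 fell (4 and 1 adjusted over the list alone), with TIP2;1 (0.76 ± 0.06) up and TIP4;1 (AT2G25810, -0.87 ± 0.19) down. Camera gave the TIP list adjusted p = 0.0261, and adjusted p = 0.149 with an estimated correlation. Cytokinin genes rose in 5 of 15 cases and 1 fell, also adjusted over the list alone, with CKX5 (AT1G75450, 0.38 ± 0.08), ARR4 (AT1G10470, 0.52 ± 0.12) and CKX3 (AT5G56970, 0.53 ± 0.13) up. Camera gave the cytokinin list adjusted p = 0.0327, and adjusted p = 0.298 with an estimated correlation. Nutrient status genes rose in 5 of 12 cases, also adjusted over the list alone, with SDI1 (1.74 ± 0.20) and the nitrate reductase gene NIA2 (AT1G37130, 0.47 ± 0.07). Camera gave the nutrient status list adjusted p = 0.0135, and adjusted p = 0.149 with an estimated correlation. Clock genes rose in 5 of 16 cases and fell in 4 (6 and 4 adjusted over the list alone, camera adjusted p = 0.226), with LHY (1.35 ± 0.07), RVE4 (1.05 ± 0.07) and CCA1 (0.86 ± 0.08) up and PRR5 (AT5G24470, -1.35 ± 0.16) down. CLV1 (0.48 ± 0.06) was the 1 of 28 meristem regulators that rose, and 2 fell (1 and 1 adjusted over the list alone). Touch genes rose in 3 of 17 cases, also adjusted over the list alone (camera adjusted p = 0.0729): CML38, TCH4 (AT5G57560, 2.43 ± 0.58) and ERF6 (AT4G17490, 1.47 ± 0.45). The touch list averaged 0.16 log2 above the col0 low mean in pip2 high replicate 1, and 1.09 and 1.51 in replicates 2 and 3, against 0.52, 0.49 and 0.05 in pip2 low replicates 1, 2 and 3. Expansin and xyloglucan genes rose in 4 of 18 cases and fell in 5 (5 and 5 adjusted over the list alone), with XTH15 up (1.87 ± 0.08). Auxin genes gave 2 rises and 3 falls of 22, salicylic acid genes 1 and 3 of 15, iron genes 2 and 1 of 7, stomatal genes 2 and 1 of 12 and floral genes 0 and 2 of 19, each also adjusted over the list alone. The anther list had 1 rise of 17 (0 adjusted over the list alone) and the vascular list had 0 of 14 by edgeR. Of the named calls in pip2, 13 of 91 were lost without at least 1 library, among them TCH4 and ERF6.

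The humidity responses of the genotypes overlapped in 3901 genes, of which 3872 moved the same way and 29 the opposite way. Of these 1871 rose and 2001 fell in both, against 383 and 416 for independent lists. Across all tested genes the fold changes correlated at 0.717 (Pearson) and 0.684 (Spearman), values across genes, which are not independent replicates. The comparisons share no library.

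**Figure D3:**
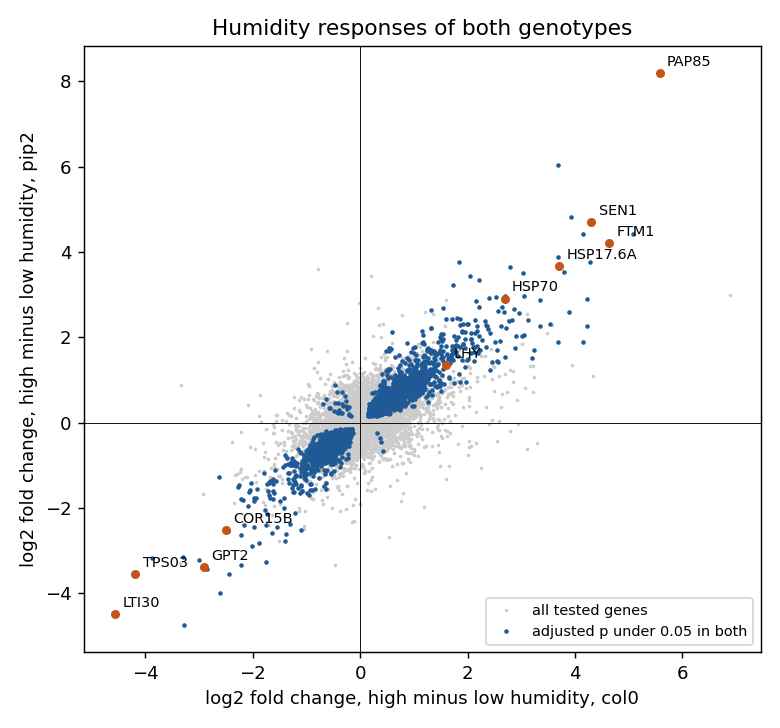
Log2 fold change of each tested gene, high minus low humidity, in col0 (horizontal axis) and in pip2 (vertical axis), with genes past adjusted p under 0.05 in both in blue and examples named. The 3872 genes that moved the same way fill the lower left and upper right, and the position of PAP85 rests on 0 to 2 counts per library in low humidity.

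The next comparison asks how pip2 differs from col0 in low humidity. Only 1 mutant genotype was measured, so the mutation cannot be told apart from other differences between the lines. Apart from PIP2;5, pip2 had higher transcripts of the endoplasmic reticulum chaperone BIP3 (AT1G09080, 5.11 ± 0.33) and of SARA1A (AT1G09180, 1.76 ± 0.16), a small GTPase of vesicle budding, and lower transcripts of a neighbouring set of chromosome 1 genes. It also had higher TAT3 (3.83 ± 0.55), UBC12 (AT3G08700, 3.66 ± 0.36), PAP19 (AT3G46120, 2.21 ± 0.33), MYB51 (2.14 ± 0.55), PGAZAT (AT2G41850, 2.13 ± 0.33), FAMT (AT3G44860, 1.96 ± 0.33), QRT2 (AT3G07970, 1.78 ± 0.33) and the crossover factor HEI10 (AT1G53490, 1.54 ± 0.15). The clock GTPase gene LIP1 fell from 46.8 ± 0.439 to 1.25 ± 0.189 CPM (AT5G64813, log2 fold change -5.23 ± 0.11), and the carbon allocation gene QQS (AT3G30720, -2.10 ± 0.26) fell too. CYP89A6 (AT1G64940, -1.81 ± 0.27), CDI (AT1G64980, -1.73 ± 0.08), CYP89A5 (AT1G64950, -1.73 ± 0.06), 4CL3 (AT1G65060, -1.68 ± 0.07), HEB1 (AT1G64960, -1.68 ± 0.07), GTG1 (AT1G64990, -1.67 ± 0.05) and APO1 (AT1G64810, -1.66 ± 0.06) fell as well and lie close together in the TAIR10.1 annotation. In all 652 genes passed, 197 higher and 455 lower, of which 43 rose and 65 fell at least 2-fold. The count was 388 without pip2 low replicate 1, 260 without the 4 libraries numbered 1 and 1084 with a replicate block. The groups did not overlap for 19.6% of tested genes, where chance gives 10%.

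The chromosome 1 neighbours were lower by nearly the same factor. From AT1G64790 to AT1G65060, 23 of 24 consecutive tested genes passed at each humidity, with a median log2 fold change of -1.61 in low humidity and -1.58 in high humidity, or 32.8% and 33.5% of the wild-type level. The tested genes on either side, AMT1;2 (AT1G64780, 0.071 ± 0.087, adjusted p = 0.806) and AT1G65070 (0.0050 ± 0.077, adjusted p = 0.986), did not pass the test in low humidity. In high humidity they did not pass either (-0.27 ± 0.086, adjusted p = 0.289, and -0.15 ± 0.076, adjusted p = 0.622). For 23 of the 24 genes every pip2 library lay below every col0 library, and the library medians in pip2 were 31.8% to 34.3% of the col0 mean. The set was singled out after its values were seen.

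**Figure D4:**
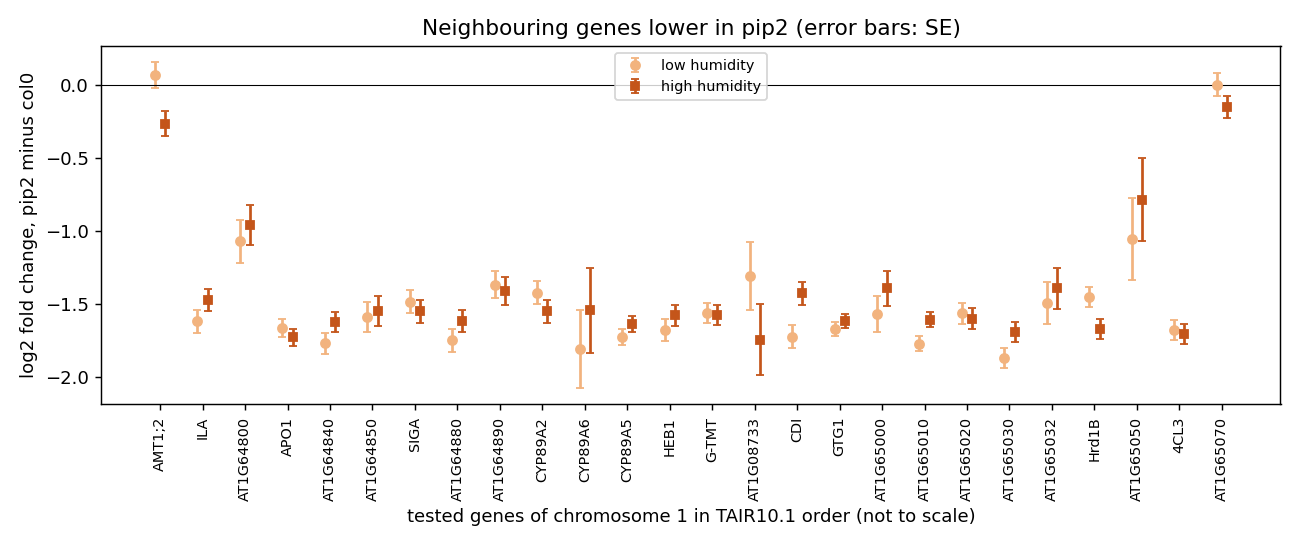
Log2 fold change of pip2 against col0 (vertical axis, error bars SE, n = 3 against 3) for 24 consecutive tested genes of chromosome 1 and the tested gene on each side, in TAIR10.1 order and not to scale, in low humidity (circles) and high humidity (squares). The 24 genes have medians of -1.61 and -1.58, and the flanking genes, at 0.071 and 0.0050 in low and -0.27 and -0.15 in high humidity, did not pass the test.

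Stress and wall genes also differed by genotype in low humidity. Jasmonate genes were higher in 7 of 16 cases (11 adjusted over the list alone), with JAZ5 (0.81 ± 0.11), OPR3 (0.30 ± 0.06), VSP2 (AT5G24770, 0.74 ± 0.14) and LOX4 (AT1G72520, 0.56 ± 0.12). Camera gave the jasmonate list adjusted p = 9.86e-11, and adjusted p = 0.116 with an estimated correlation. Dehydration genes were higher in 4 of 30 cases (7 adjusted over the list alone): P5CS1 (0.63 ± 0.07), RAB18 (AT5G66400, 1.23 ± 0.15), GOLS1 (AT2G47180, 0.81 ± 0.17) and ABI1 (AT4G26080, 0.26 ± 0.07). The GOLS1 call was lost with the replicate block (adjusted p = 0.0874). Camera gave the dehydration list adjusted p = 8.11e-06, and adjusted p = 0.145 with an estimated correlation. In the heat shock list BIP3 was higher and 4 of 16 members were lower (2 higher and 6 lower adjusted over the list alone), with HSFA2 (-1.54 ± 0.17), HSP101 (-0.67 ± 0.09) and HSP70 (-1.21 ± 0.17). Camera gave the heat shock list adjusted p = 2.45e-05, and adjusted p = 0.116 with an estimated correlation. Expansin and xyloglucan enzyme genes were lower in 4 of 18 cases (7 adjusted over the list alone): XTH15 (-0.75 ± 0.08), XTH9 (AT4G03210, -0.63 ± 0.07), EXPA6 (AT2G28950, -0.36 ± 0.06) and XTH18 (AT4G30280, -3.56 ± 0.92). Camera gave the expansin and xyloglucan list adjusted p = 7.61e-06, and adjusted p = 0.116 with an estimated correlation. Of the PIP aquaporins 4 of 13 were lower, also adjusted over the list alone: PIP2;5, PIP1;3 (-0.31 ± 0.06), PIP2;7 (AT4G35100, -0.34 ± 0.07) and PIP1;4 (AT4G00430, -0.25 ± 0.06). Camera gave the PIP list adjusted p = 9.35e-07, and adjusted p = 0.116 with an estimated correlation. PIP2;5 itself is in that list, which was not tested without it. TIP2;1 (-0.32 ± 0.06) and TIP1;1 (-0.28 ± 0.07) were lower among 7 TIP genes (3 adjusted over the list alone, camera adjusted p = 0.0523).

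Smaller sets completed the low humidity comparison. Wax and cutin genes were lower in 3 of 29 cases (6 adjusted over the list alone): LTPG2 (-0.40 ± 0.07), KCS1 (AT1G01120, -0.27 ± 0.06) and CER4 (-0.34 ± 0.08). Camera gave the wax and cutin list adjusted p = 2.46e-05, and adjusted p = 0.371 with an estimated correlation. Nutrient status genes were lower in 3 of 12 cases (6 lower and 1 higher adjusted over the list alone): NIA2 (-0.48 ± 0.07), SDI1 (-1.25 ± 0.21) and AT1G04770 (-0.65 ± 0.11). Camera gave the nutrient status list adjusted p = 0.0314, and adjusted p = 0.145 with an estimated correlation. IAA19 (-0.58 ± 0.12) was the 1 auxin gene of 22 that was lower (3 adjusted over the list alone; camera adjusted p = 0.0315, and adjusted p = 0.116 with an estimated correlation). FER1 (-0.68 ± 0.12) and TT7 (-0.46 ± 0.10) were lower, each the 1 member of its list. No salicylic acid or immunity gene passed, and that list was called as higher (camera adjusted p = 0.00319, and adjusted p = 0.272 with an estimated correlation). The photosynthetic, vascular, anther, meristem, floral, stomatal, cell cycle, cytokinin, clock and touch lists had 0 members past the test by edgeR, over all genes and adjusted over the list alone. Of the 49 named calls 15 were lost without at least 1 library, among them MYB51, XTH18, ABI1, GOLS1, PIP1;3, PIP1;4, TIP1;1, VSP2, LOX4, OPR3, CER4, KCS1, IAA19, FER1 and TT7.

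The genotypes were compared in high humidity in the same way. BIP3 (3.45 ± 0.30), UBC12 (3.76 ± 0.34), HEI10 (1.86 ± 0.15), PGAZAT (1.81 ± 0.30), SARA1A (0.997 ± 0.15) and the endoplasmic reticulum co-chaperone ATERDJ3A (AT3G08970, 1.17 ± 0.09) were higher in pip2, as were PAP85 (1.27 ± 0.25), MLO9 (AT1G42560, 1.24 ± 0.25), SCRL19 (AT3G27503, 1.24 ± 0.19) and RIC5 (AT3G23380, 1.17 ± 0.25). LIP1 (-5.75 ± 0.12), QQS (-2.24 ± 0.25) and IOS1 (AT1G51800, -1.68 ± 0.35) were lower, together with 6 of the chromosome 1 neighbours: APO1 (-1.73 ± 0.06), 4CL3 (-1.71 ± 0.07), Hrd1B (AT1G65040, -1.68 ± 0.07), CYP89A5 (-1.64 ± 0.06), GTG1 (-1.62 ± 0.05) and HEB1 (-1.58 ± 0.07). In all 129 genes passed, 44 higher and 85 lower, of which 20 rose and 38 fell at least 2-fold. The count was 77 without pip2 high replicate 3 and 249 by DESeq2. The share of higher genes depended on the test, with 44.6% by DESeq2 and 50.5% of 107 genes in a fit of only the 6 libraries compared. The groups did not overlap for 14.0% of tested genes, where chance gives 10%. The heat shock list had 1 member higher, BIP3, and 5 of 16 lower (1 and 8 adjusted over the list alone), with HSFA2 (-1.41 ± 0.15), HSP101 (-0.77 ± 0.08) and ROF1 (AT3G25230, -0.47 ± 0.09). Camera gave the heat shock list adjusted p = 3.08e-08, and adjusted p = 0.0674 with an estimated correlation.

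PIP2;5 was the 1 other list member past the threshold in high humidity. Camera called 6 further lists, although none of their members passed over all genes by edgeR. The touch list was lower (camera adjusted p = 0.00173, and adjusted p = 0.661 with an estimated correlation), as were the vascular list (camera adjusted p = 0.00607, and adjusted p = 0.661 with an estimated correlation), the wax list (camera adjusted p = 0.000429, and adjusted p = 0.661 with an estimated correlation) and the flavonoid list (camera adjusted p = 0.000687, and adjusted p = 0.351 with an estimated correlation). The anther list was higher (camera adjusted p = 0.0119, and adjusted p = 0.661 with an estimated correlation), as was the cytokinin list (camera adjusted p = 0.0206, and adjusted p = 0.55 with an estimated correlation). By fry none of these 6 lists was called, with adjusted p from 0.0963 (flavonoid) to 0.531 (touch and anther). Adjusted over the list alone, 1 vascular and 1 flavonoid gene were lower and 1 cytokinin gene was higher. Across the humidities 93 genes passed in both genotype comparisons, 92 in the same direction (30 higher and 62 lower, against 0.396 and 1.77 for independent lists). The calls of ROF1, IOS1, PAP85, MLO9 and RIC5 were lost without at least 1 library.

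The last comparison asks whether the mutant responds to humidity differently from the wild type, by the interaction of genotype and humidity. The named genes whose response was higher in pip2 included EXO (AT4G08950, 1.34 ± 0.11), a growth gene of the cell wall, and the arabinogalactan protein genes FLA13 (AT5G44130, 1.198 ± 0.21) and AGP7 (AT5G65390, 1.18 ± 0.14). The xyloglucan enzyme genes XTH16 (AT3G23730, 1.15 ± 0.09), XTH15 (0.998 ± 0.11) and XTH9 (0.68 ± 0.10) were others. The proline dehydrogenase gene ERD5 (AT3G30775, 1.16 ± 0.18) and NIA2 (0.50 ± 0.10) were in the same direction. EXO went from 318 ± 14 to 230 ± 24 CPM in col0 and from 105 ± 7.5 to 192 ± 11 in pip2. The response was lower in pip2 for the thionin gene THI2.2 (AT5G36910, -1.55 ± 0.23), for CYP79B2 (AT4G39950, -1.09 ± 0.21) and CYP83B1 (AT4G31500, -0.85 ± 0.15), enzymes of indole glucosinolate synthesis, for the hexose transporter gene MSS1 (AT5G26340, -0.80 ± 0.16), and for JAZ5 (-0.81 ± 0.17), LOX3 (-0.59 ± 0.11) and P5CS1 (-0.51 ± 0.10).

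In all 97 genes passed the interaction test, 78 with a higher and 19 with a lower response in pip2. The median log2 fold change of the 78 was -0.33 in col0 and 0.37 in pip2, and 75 of them passed as lower in pip2 in low humidity while 2 passed between the genotypes in high humidity. Expansin and xyloglucan genes had 2 of 18 members past, both higher (3 adjusted over the list alone; camera adjusted p = 0.00834, and adjusted p = 0.223 with an estimated correlation). Jasmonate genes had 2 of 16 past, both lower (4 adjusted over the list alone; camera adjusted p = 2.12e-07, and adjusted p = 0.223 with an estimated correlation). Of 30 dehydration genes P5CS1 passed as lower (10 adjusted over the list alone), and of 12 nutrient genes NIA2 passed as higher (3 adjusted over the list alone, camera adjusted p = 0.0553). Camera gave the dehydration list adjusted p = 2.5e-08, and adjusted p = 0.201 with an estimated correlation. PIP aquaporins had none past over all genes and 3 of 13 adjusted over the list alone, the smallest p being that of PIP1;3 (0.37 ± 0.09, adjusted p = 0.0808). Camera gave the PIP list, PIP2;5 included, adjusted p = 0.000108, and adjusted p = 0.201 with an estimated correlation. TIP aquaporins had none past over all genes and 3 of 7 adjusted over the list alone (camera adjusted p = 0.0162, and adjusted p = 0.201 with an estimated correlation). The touch list, with 0 members past by edgeR, was called as lower (camera adjusted p = 0.000108, and adjusted p = 0.365 with an estimated correlation), as were the salicylic acid list (camera adjusted p = 0.00443, and adjusted p = 0.223 with an estimated correlation), the flavonoid list (camera adjusted p = 0.0125, and adjusted p = 0.223 with an estimated correlation) and the meristem list (camera adjusted p = 0.041, and adjusted p = 0.528 with an estimated correlation). The cytokinin list was called as higher (camera adjusted p = 0.00853, and adjusted p = 0.223 with an estimated correlation). The heat shock, photosynthetic and clock lists were not called by camera (adjusted p = 0.257, 0.981 and 0.0963). The count depended on single libraries and on the test, from 39 genes without col0 high replicate 2 to 112 without pip2 high replicate 2, with 186 by DESeq2 and 10 without the 4 libraries numbered 1. The calls of EXO, XTH16, XTH15, XTH9, AGP7 and THI2.2 held without each library in turn, although that of XTH9 was lost by limma on log2(TPM + 1) and log2(TPM + 0.1), and those of the other 9 named genes were lost without any of 5 libraries (LOX3) to any of 10 (JAZ5 and MSS1).

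**Figure D5:**
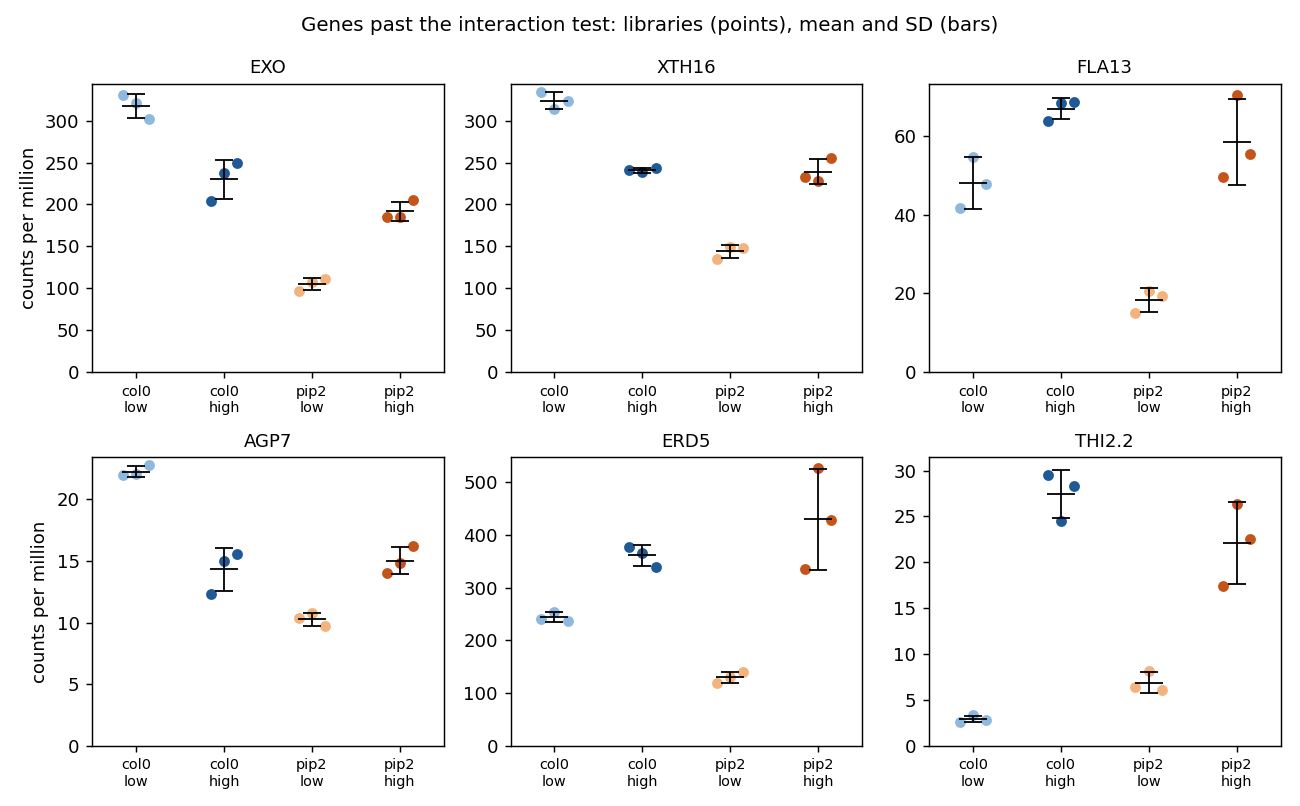
CPM (vertical axes, linear, from 0) of 6 genes past the interaction test in the 4 groups, with 1 point per library and bars for mean and SD (n = 3). EXO and XTH16 fall with high humidity in col0 and rise in pip2, from 105 to 192 and from 144 to 239 CPM.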

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

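All tests of explanations in this part were chosen after the result was seen, except the second cold list and the counts over other splits of the libraries.

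These results drew a closer look because the humidity response differed between the genotypes by the interaction test itself. The test called 97 genes. The difference of the response, pip2 minus col0 in log2, was 1.34 for EXO, 1.198 for FLA13, 1.18 for AGP7, 1.16 for ERD5, 1.15 for XTH16, 0.998 for XTH15, 0.68 for XTH9 and 0.50 for NIA2. It was -1.55 for THI2.2, -1.09 for CYP79B2, -0.85 for CYP83B1, -0.81 for JAZ5, -0.80 for MSS1, -0.59 for LOX3 and -0.51 for P5CS1.

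The first pattern is that 78 of the 97 genes had a higher response in pip2, with 75 of them lower in pip2 at low humidity. All 78 kept their sign and at least 0.5 of the difference without each of the 12 libraries. They were picked by the test on these same 12 libraries, so that outcome was nearly fixed and leaves open whether 1 library decides. The number of genes past the test went from 39 without col0 high replicate 2 to 112 without pip2 high replicate 2. With DESeq2 size factors 73 of the 78 passed. Those factors moved the median difference over all genes only from 0.015 to 0.0058, so the scaling was hardly tested and stays open. A different share of other tissues in pip2 at low humidity stays open too, with marker medians there of 0.066 for photosynthetic, -0.064 for vascular and -0.0072 for anther genes, as does an untested difference between the genotypes in the humidity response. Of 100 splits drawn from 200, 3 gave at least 97 genes, the real one included, and the others gave 2283 and 716; every other split exchanges libraries between the humidities and so mixes in the humidity response, so the share leaves chance undecided.

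The second pattern is that 23 of 24 neighbouring genes of chromosome 1 passed as lower in pip2 at each humidity. The longest run of lower genes in 1000 random orders was 3, against 23 called genes here, which argues against chance clustering. For 23 of the 24 genes every pip2 library lay below every col0 library. The genes were picked by their difference in these same libraries, so that separation was largely fixed and is no test of 1 or 2 aberrant libraries. As a description, each pip2 library had a block median of 31.8% to 34.3% of the col0 mean. A candidate explanation is a dose difference of 1 chromosome segment between the lines: 22 genes lay within 0.4 log2 of the median at both humidities and 0 passed the interaction test by edgeR. The interaction test recovered 17.9% of simulated changes of 0.5 log2, so the 0 is weak evidence. The levels of 32.8% and 33.5% of wild type were not matched to any copy number. Whether either line gained or lost a segment was not tested. PIP2;5 (AT3G54820) carries an identifier of another chromosome, and whether the lower genes go with its mutation was not tested.

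The third pattern is that clock, heat shock and dehydration genes differed with humidity in both genotypes. Of 10 clock genes, 8 moved past the test in both genotypes as a shifted time of day at harvest would move them, morning genes up and evening genes down. The evening gene TOC1 did not pass in col0 (0.071 ± 0.074) or in pip2 (0.12 ± 0.075). LUX passed as lower in col0 (-0.24 ± 0.087) but not in pip2 (0.039 ± 0.088). A shifted time of day cannot be separated from humidity by the design. A difference in tissue temperature may also contribute: a second list of cold-induced genes had a median log2 fold change of -0.40 in col0, with 4 of 8 falling and 1 rising, and of -0.58 in pip2, with 5 falling and 1 rising, which leaves that explanation undecided. A different share of other tissues stays open: in col0 the photosynthetic median was 0.37 and the vascular 0.30, and the anther median of -0.48 was in a list without a camera call. In pip2 the photosynthetic median was 0.37, the vascular 0.068 and the anther -0.0099. An effect of air humidity itself remains open beside time, temperature and tissue share.

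The comparisons of 3 against 3 libraries have 10 splits each, too few for a share under 0.05. The real split alone reached its count in each (1 of 10). Every other split mixes libraries of the compared groups, so a real difference adds to the spread and lowers its count. These counts therefore leave chance undecided. The real counts were 6614, 5294, 652 and 129 genes, and the highest of the other splits gave 0, 0, 0 and 14, the splits that also part every same-numbered pair included.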

How the results depend on the processing

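The alternatives without the chromosome 1 neighbours and without the 4 libraries numbered 1 were chosen after seeing the data, and the others were planned. No result reversed among those past the threshold. List outcomes with no call changed sign 61 times, counting each of the 110 list results once per alternative. With an absolute log2 fold change of at least 1 the counts were 707 (col0 humidity), 638 (pip2 humidity), 108 (genotype, low), 58 (genotype, high) and 13 (interaction), since that threshold removes smaller changes. The DESeq2 Wald test gave 249 for the genotype at high humidity and 186 for the interaction, and limma on log2(TPM + 1) and on log2(TPM + 0.1) gave 42 and 42 for the interaction; the cause was not tested. Limma also moved the share of higher calls for the genotype at low humidity to 40.3% and 40.8%, against 197 of 652. For the genotype at high humidity that share was 44.6% by DESeq2, 50.5% with only the 6 libraries compared, 51.6% with the replicate block and 23.3% without col0 high replicate 3, against 44 of 129. For the interaction it went from 66.1% without pip2 high replicate 2 to 92.3% without col0 high replicate 2, against 78 of 97. Without the 4 libraries numbered 1, with fewer samples, the counts were 260 (genotype, low) and 10 (interaction), and without the chromosome 1 neighbours 613 and 95 genes passed between the genotypes.

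Leaving out each library gave 4826 to 6974 genes for humidity in col0, 4030 to 5441 in pip2, 388 to 810 for the genotype at low humidity, 77 to 162 at high humidity and 39 to 112 for the interaction. At low humidity the count was 428 without col0 low replicate 1, 430 without col0 low replicate 3 and 388 without pip2 low replicate 1. At high humidity it was 83 without col0 high replicate 2 and 77 without pip2 high replicate 3. For the interaction it was 51, 50 and 49 without col0 low replicates 1, 2 and 3, 62, 39 and 51 without col0 high replicates 1, 2 and 3, and 46 and 59 without pip2 low replicates 1 and 3. Of the calls of named genes, 15 of 96, 13 of 91, 15 of 49, 5 of 23 and 9 of 15 were lost without at least 1 library, in the order of the comparisons above, and 18, 14, 16, 6 and 10 under at least 1 of all the alternatives fixed beforehand. Without pip2 high replicate 2 the counts were 810 for the genotype at low humidity and 112 for the interaction.

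With the replicate block 7576 genes passed for humidity in col0 and 6341 in pip2, against 6614 and 5294 without it. The replicate block also gave 1084 and 314 genes for the genotype at low and high humidity, and 197 for the interaction. It gave 149 genes shared by the genotype differences in 1 direction (92 without it). For humidity in col0 and the genotype at low humidity, every same-numbered pair correlated over 0.1. There the block changed no call of a named gene or list other than those of GRP19, GOLS1 and the auxin list. Over all groups 12 of 18 same-numbered pairs correlated over 0.1, and 4 of 12 libraries correlated best with their own number in every other group. Of the list calls, 43 were lost with an estimated correlation and the heat shock list kept its calls for humidity in both genotypes. By fry 19 list calls were lost and 13 were gained. In the simulation 17.9% of interaction changes of 0.5 log2 were recovered, against 47.8% for humidity in col0 and 41.8% for the genotype at low humidity.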

Other observations

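The test of the second list of endoplasmic reticulum genes was set before its values were seen, though the list was chosen after the genotype results were seen, and the genes described here were picked after their values were seen.

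Outside the chromosome 1 neighbours, 70 genes passed in both genotype differences, 30 higher and 39 lower in pip2, PIP2;5 included, and ACR4 (AT1G69040) in opposite directions. The genes named next were picked by hand, and no enrichment was tested. Among the higher ones ATERDJ3A had log2 fold changes of 1.21 ± 0.09 at low and 1.17 ± 0.09 at high humidity, and the disulfide enzyme gene ERO1 (AT1G72280) 0.92 ± 0.11 and 0.80 ± 0.11. BZIP60 (AT1G42990), a regulator of the unfolded protein response, had 0.77 ± 0.07 and 0.50 ± 0.07, and the disulfide isomerase gene PDIL2-3 (AT2G32920) 0.56 ± 0.07 and 0.68 ± 0.07. Among the lower ones were HSP81-2 (AT5G56030, -0.60 ± 0.09 and -0.45 ± 0.09), Hop3 (AT4G12400, -0.55 ± 0.11 and -0.75 ± 0.10), cpHsc70-2 (AT5G49910, -0.59 ± 0.07 and -0.42 ± 0.07) and MTHSC70-2 (AT5G09590, -0.34 ± 0.09 and -0.42 ± 0.09). HSP81-2 and HSP81-3 are close copies, so their values are uncertain.

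The hypothesis of a general rise of the endoplasmic reticulum chaperone system with genotype was left open. The rule set beforehand counted a median below 0.1 at low humidity against it, in a list made without the genes already seen as higher. In these 17 further genes the median log2 fold change was -0.13 at low humidity, where BI1 was higher and CNX1 lower. There 4 of the 17 values were positive, 7 genes had an unadjusted p under 0.05 and 3 passed by DESeq2. Camera gave the list an unadjusted p = 0.0317, and p = 0.486 with an estimated correlation. At high humidity the median was -0.0044, and 0 passed by edgeR (1 at an unadjusted p under 0.05) and 0 by DESeq2. The 17 genes thus did not rise as a set. A list that left out the called genes does not decide about the whole system, a limit that the rule did not state.

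Some genes were nearly silent in 1 genotype. AT1G18830 had 5 to 11 counts per library in col0 and 858 to 1461 in pip2. AT1G75945 had 251 to 333 counts in col0 and 0 to 3 in pip2, and AT3G05955 had 53 to 92 and 0 to 2. AT1G06957 had 134 to 336 counts in col0 and 0 in all 6 pip2 libraries. The adjacent identifiers UBC12 (AT3G08700) and UBC11 (AT3G08690), ubiquitin-conjugating enzyme genes, went in opposite directions, at 3.66 ± 0.36 and -1.23 ± 0.07 at low humidity, and 3.76 ± 0.34 and -1.13 ± 0.07 at high humidity. The causes were not tested.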
